A study of Homo sapiens with 4 samples.

How the data were processed

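Poly(A)-selected, stranded RNA libraries (TruSeq stranded mRNA kit, total RNA from the miRNeasy kit, per the labels' protocols) were made from HCT116 cells. The groups were 2 libraries of cells transfected with an empty vector (EV control) and 2 libraries of C14orf159 knockout cells (KO), taken from the labels. The control columns are named AAVS1 and the knockout columns sgDGLUCY, per the file headers; AAVS1 is a genomic site often targeted as a neutral control. Whether the controls carried an empty vector or a guide against that site was not settled, and EV control stands for them as labelled. The deposited values are FPKM per gene symbol, fragments per kilobase of transcript and per M (mega) fragments, per the file headers. TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cuffnorm 2.2.1 and the genome build hg19 are named per the submitters' processing notes. The gene annotation, the use of strand in counting and the scaling between libraries are not given in the sources used here. No count of reads was used, and values were taken as deposited.

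FPKM of very short genes rest on few fragments, since the division by a short effective length gives 1 fragment a high value. The value of 1 fragment was therefore estimated in 2005 genes with a single annotated transcript (GENCODE release 29) of 1000 to 6000 nt. FPKM was multiplied by transcript length in kilobases, and the median was taken of products between 0.06 and 0.1 (107 to 118 genes per library). The value of 1 fragment per kilobase came to 0.0770, 0.0747, 0.0802 and 0.0777 FPKM in EV control 1, EV control 2, KO 1 and KO 2, hence 12.99, 13.39, 12.47 and 12.86 M fragments. The window was preset and bounds the result, so these depths are rough estimates and no library totals. For ratios between libraries, the commonest ratio to EV control 1 was used instead. It was 0.974 in EV control 2, 1.06 in KO 1 and 1.03 in KO 2. A total of 19 genes were listed at 0 in 1 library and at 20 FPKM or more in the other 3, and all 19 were small RNA genes, so a value of 0 is reported as listed at 0.

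Values were transformed to log2(FPKM + 1), and genes with an FPKM of at least 1 in at least 2 of the 4 libraries were tested (12701 genes, 144 of them small RNA genes). Group differences were fitted with limma 3.58.1 (lmFit and eBayes with a mean-variance trend) in R 4.3.3, with the group as the sole term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. With 2 libraries per group the moderated variance rests on 2.82 prior degrees of freedom in addition to the residual ones. Log2 changes are KO minus EV control.

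A set of 36 gene lists was fixed, of which the 32 with at least 5 tested members were tested with camera at its preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry were run as alternatives. With an estimated correlation, camera takes its p-values from the residual degrees of freedom of 4 libraries. These are few, so a list could hardly pass in that setting. Fry's p-value tests whether the genes of a list move on balance in a common direction, and its mixed p-value whether they change in either direction, without comparison with other genes. Members of a list were also adjusted over the list alone.

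Genes were named by rule: the targeted gene; up to 12 genes per direction with the largest fold change among those that passed, with groups that do not overlap and a mean of at least 3 FPKM in the higher group, filled up by the smallest p-values; and up to 4 genes per list with the smallest p-values. Unnamed loci, small RNA symbols and replication-dependent histones were left out of the largest-fold part, although RNVU1-19 passed that rule by its symbol. A few genes and 1 gene list that the rule or the tests cover are not reported here. Other list members, the small RNA calls and the genes of chromosome 14 were named after their values were seen. The groups, the tests, the lists, the naming rule and the first set of alternatives were chosen before the data were examined.

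The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, limma without the trend, robust limma-trend, a replicate block, a 1.5-fold minimum and leaving out each library in turn. Added after the data were seen were a fit without small RNA genes, also without either KO library, a correction for GC content and transcript length (lowess, GENCODE values for 97.6% of tested genes), and a fit without the distal genes of chromosome 14. Gene order was taken from the RefSeq gene table of assembly GRCh38.p14 by symbol or synonym (98.4% of tested genes matched) and used for order alone, since the deposited values rest on hg19; coordinates are not printed for that reason. For the order scan, 9031 genes with a mean of at least 5 FPKM were placed in order, and medians were taken over 24333 windows of 41 genes, in 3 comparisons. The single split of each chromosome that best separated the means on its sides was also scored (69 splits, at least 15 genes per side). Intervals of the stretch are from 2000 bootstrap draws over genes, which treat neighbouring genes as independent.

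The test was tried on simulated data, in 20 draws with 200 changed genes each over 12701 genes for the comparison of KO with EV control. It recovered 73.4% of 2-fold and 96.2% of 4-fold changes, and 5.09% of calls were false. Unchanged lists were called in 0 of 620 tests and a list shifted by 0.3 on the log2 scale in 20 of 20 draws. The simulated genes varied independently and alike in both groups, and changed genes were taken above a minimum mean level. In these data the estimated correlation within a list reached 0.93 (ribosomal proteins). KO replicates also differed more than EV control replicates (robust SD of log2 ratios 0.21 and 0.079 at 30 to 100 FPKM). The simulated rates therefore do not carry over to these data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the other steps.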

Results

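RNA sequencing was carried out on HCT116 cells, an established human colorectal cancer line, in which C14orf159 had been knocked out, and on control cells of the same line, transfected with an empty vector per the labels, whereas the file headers name the control columns AAVS1. C14orf159 is named DGLUCY in current nomenclature and encodes a protein of the mitochondrial matrix. Each group held 2 libraries, called EV control replicates 1 and 2 and KO replicates 1 and 2. Each library was given as FPKM for 26255 genes, of which 12701 reached the minimum level and were tested. From the value of 1 fragment in genes with a single transcript, the libraries held an estimated 12.99, 13.39, 12.47 and 12.86 M fragments (mega) in the order EV control 1, EV control 2, KO 1 and KO 2. These depths are rough, since the preset window of values bounds them. Small RNA genes took between 67.7% and 70.9% of the summed FPKM, most of it from MIR6723 alone (61.7% to 66.1%). This is no share of fragments, since 1 fragment on a very short gene has a high FPKM. Nothing in the labels says that replicates came from separate cultures or clones. The p-values measure the spread between these libraries, which may be technical in part. For the KO libraries, 66 expressed chromosome 14 genes described below had medians of 56.6% and 102.9% of the EV control level. This argues against the KO libraries being repeats of the same cells, and what sets them apart is not given in the labels.

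The targeted gene was examined first, as a check of the labels. C14orf159 stood at 16.2 and 16.4 FPKM in the EV control libraries, at 2.52 FPKM in KO replicate 1 and at 10.8 FPKM in KO replicate 2. The KO libraries thus kept 15.5% and 66.2% of the EV control mean, both lower than either control. The difference between the groups was -1.42 on the log2(FPKM + 1) scale (SE 0.57) and did not pass the test (limma-trend, adjusted p = 0.314). With KO replicate 1 left out the difference was -0.55, and with KO replicate 2 left out it was -2.30. Each of these fits leaves a lone KO library, whose spread is taken from the EV controls, so their p-values are not given. In KO replicate 1 the neighbours of C14orf159 were lower as well, as described below. The level of this transcript does not show whether the protein was lost, and the position of the edit within the gene is not given in the sources used here.

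The spread between libraries was compared next. Among 2069 genes with a mean of 30 to 100 FPKM, the robust SD of the log2 ratio was 0.079 between the EV control replicates and 0.21 between the KO replicates, as wide as the 0.19 to 0.22 between EV and KO libraries. The first principal component (41.02% of the variance) set KO replicate 2 apart and left KO replicate 1 between the EV controls. On the second (37.5%) KO replicate 1 stood far from the rest at 0.820, and KO replicate 2 (-0.0586) lay above the EV controls (-0.250 and -0.512). Both KO libraries lay above both EV control libraries for 26.5% of tested genes and below them for 25.6%. Chance would give 16.7% in each direction if all 4 libraries varied alike. The wider spread of the KO libraries raises that share by an amount that was not determined, so the excess does not show a shared effect.

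To ask which genes respond to loss of C14orf159, which the study set out to link to migration, invasion and spheroid growth, the KO libraries were compared with the EV controls gene by gene. UGP2, which makes UDP-glucose, rose from 16.8 ± 0.190 to 38.7 ± 1.04 FPKM (SD, n = 2 per group). ACSL5, a long-chain acyl-CoA synthetase, rose from 86.4 ± 3.44 to 199.8 ± 5.77 FPKM. The transmembrane protein gene TMEM74B rose from 8.05 ± 0.234 to 20.1 ± 1.13 FPKM. The transcription factor gene GATA2 fell from 11.4 ± 0.872 to 3.21 ± 0.0436 FPKM. On the log2(FPKM + 1) scale, which understates the change of low genes, these differences were 1.16 (SE 0.075), 1.20 (SE 0.083), 1.22 (SE 0.086) and -1.56 (SE 0.098).

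In all, 7 genes were higher and 7 lower in the KO libraries (limma-trend, Benjamini-Hochberg adjusted p under 0.05). UGP2 (adjusted p = 0.0450), ACSL5 (0.0484), TMEM74B (0.0484) and GATA2 (0.0428) were the 4 that are not small RNA genes. The other 10 were the small RNA genes MIR6516, MIR6126, RNVU1-19 and SNORA51, all higher, and SNORA68, SNORA14B, MIR6753, SNORA5C, MIR671 and SNORA60, all lower. Of these, 9 were listed at 0 in both libraries of a group: RNVU1-19, a variant U1 small nuclear RNA, was listed at 0 in both EV controls and at 6.10 and 5.92 FPKM in the KO libraries. The values above 0 of all 10 stood in ratios of whole numbers up to 5 between replicates, within 0.5%, once the value of 1 fragment was taken out. Leaving small RNA genes out, a choice made after seeing the data, gave 0 higher and 0 lower genes (limma-trend, smallest adjusted p = 0.0531, 2171 genes at an unadjusted p under 0.05). No gene other than a small RNA gene passed without EV control replicate 1 or without EV control replicate 2, where GATA2 had adjusted p = 0.134 and 0.244. Without a filter on low values all 4 of those calls ended (adjusted p from 0.105 for UGP2 to 0.165 for GATA2 and TMEM74B), and in limma without the trend UGP2, ACSL5 and TMEM74B did not pass (0.06145 each) while GATA2 did. TMEM74B also did not pass with quantile normalization (0.0642) or with a correction for GC content and length added after seeing the data (0.0918). In limma-trend with a replicate block, UGP2 (0.0535), ACSL5 (0.0631) and TMEM74B (0.0520) did not pass, while GATA2 did (0.0249). Without KO replicate 1 the counts were 1381 higher and 841 lower, and without KO replicate 2 they were 799 higher and 881 lower, the lone KO library being assumed to vary like the EV controls.

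Further genes were named by the smallest p-values and are given as values, since they did not pass the threshold. On the higher side, PROM1, which encodes the surface glycoprotein CD133, had 2.06 ± 0.155 FPKM in EV control and 9.23 ± 1.39 in KO cells (adjusted p = 0.0515). NOTUM, a secreted enzyme that inactivates Wnt proteins, had 3.37 ± 0.302 and 10.96 ± 1.64 FPKM (adjusted p = 0.0891). NDRG1 had 44.0 and 88.2 FPKM, the long non-coding RNA OLMALINC 18.6 and 32.9, ENKD1 7.73 and 14.8, FAM71E1 3.81 and 10.6, HIAT1 6.59 and 14.4, and HLA-DMB 1.34 and 3.86. On the lower side, ANXA3, an annexin, had 204 ± 2.63 FPKM in EV control and 103 ± 1.20 in KO cells (adjusted p = 0.0553). The T-box factor gene TBX3 had 5.86 and 1.70 FPKM, the proteoglycan gene VCAN 5.39 and 1.88, MALT1 19.5 and 8.99, TSPAN1 35.8 and 20.5, and SOCS6 19.05 and 11. The collagen gene COL12A1 had 19.99 and 11.6 FPKM, and FRAS1 10.5 and 5.36. HNRNPH2 had 18.8 and 10.8 FPKM and the pseudogene ATP5EP2 19.02 and 1.55, both uncertain because a close paralog or parent gene can share their reads.

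**Figure D1:**
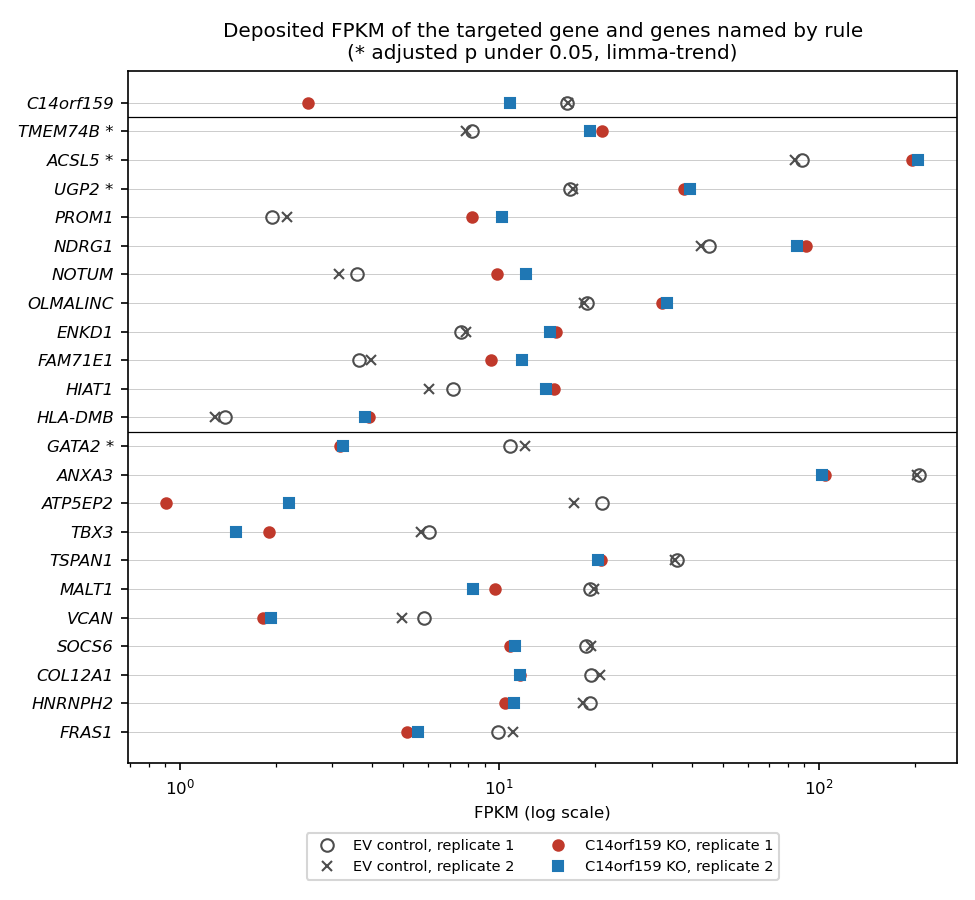
FPKM on a log scale (x axis) of C14orf159 and genes named by rule (y axis), 1 symbol per library; RNVU1-19 is left out because it is listed at 0 in the EV controls. C14orf159 stands at 2.52 FPKM in KO replicate 1 and 10.8 in KO replicate 2. The KO libraries lie close together for UGP2 (37.97 and 39.4 FPKM) and GATA2 (3.18 and 3.24 FPKM). These genes were named for passing a test that favours a small spread between replicates.

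The title of the series names Wnt/β-catenin signalling, so its target genes were examined as a list. Of 26 tested Wnt/β-catenin target genes, 6 were higher and 0 lower adjusted over the list alone. They were NOTUM (list-alone adjusted p = 0.00366), the Frizzled-removing ubiquitin ligase gene RNF43 (8.13 and 24.8 FPKM, 0.0119), the ephrin receptor genes EPHB3 and EPHB2, and the TCF/LEF factor genes TCF7L1 and TCF7. NOTUM and RNF43 are known as feedback inhibitors of the pathway. Over all genes tested, 0 members passed in limma-trend, with 7 higher and 1 lower at an unadjusted p under 0.05. At that unadjusted level, 1172 of all 12701 tested genes were higher and 917 lower. Widely used targets gave AXIN2 3.66 and 4.93, MYC 195 and 175, CCND1 134 and 143, SOX9 47.0 and 42.2, CD44 186 and 163, and DKK1 63.6 and 46.9 FPKM in EV control and KO cells, and none of these passed. The list as a whole was shifted upwards, with a median log2 change of 0.21 (camera with a preset correlation, adjusted p = 0.0101; adjusted p = 0.408 with an estimated correlation). In fry, which asks whether the genes of a list move on balance in a common direction, it was the 1 list of 32 that passed (adjusted p = 0.0161). Without KO replicate 1 its camera adjusted p was 0.0892.

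Wnt ligands, receptors and pathway components were not shifted (41 tested, median log2 change 0.04, adjusted p = 0.385), and 0 of them passed in limma-trend over the list alone or over all genes, with 8 higher and 2 lower at an unadjusted p under 0.05. CTNNB1, the β-catenin gene, had 137 and 115 FPKM, WNT3A 0.489 and 1.52, and WNT6 0.341 and 1.82. Among 15 colorectal stem cell genes, PROM1 was higher adjusted over the list alone (0.000913) and BMI1 had 4.82 and 8.08 FPKM (0.0637), while the list was not shifted (adjusted p = 0.620). Of 9 tested intestinal differentiation genes, 2 were higher adjusted over the list alone, and the list was not shifted (adjusted p = 0.652). DPP4 was among them (0.348 and 1.65 FPKM).

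Genes tied to migration and invasion were next compared, since these are the behaviours the study asked about. The mesenchymal list was shifted upwards (16 tested, median log2 change 0.27, adjusted p = 0.0101; adjusted p = 0.408 with an estimated correlation). In it LOXL2 (4.86 and 8.28 FPKM), TPM1 (13.7 and 19.3) and COL1A1 (4.58 and 6.79) were higher and 0 genes lower adjusted over the list alone. Epithelial junction and polarity genes were shifted upwards as well (37 tested, median log2 change 0.09, adjusted p = 0.0185; adjusted p = 0.408 with an estimated correlation). There the claudin gene CLDN3 (9.97 and 21.4 FPKM) and the transcription factor gene GRHL1 (2.32 and 5.12) were higher adjusted over the list alone. CDH1, the E-cadherin gene, had 22.8 and 27.2 FPKM. The mesenchymal call ended without KO replicate 2 (adjusted p = 0.0501) and the epithelial call without KO replicate 1 (0.0515).

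Proteases and invasion genes were not shifted as a list (26 tested, adjusted p = 0.125), although the urokinase receptor gene PLAUR (18.2 and 27.3 FPKM), the plasminogen activator gene PLAT (5.38 and 11.02) and TIMP2 (33.7 and 45.6) were higher adjusted over the list alone. Integrins and extracellular matrix genes were not shifted (32 tested, adjusted p = 0.268) except without KO replicate 2 (0.00455), and there COL13A1 was higher and COL12A1 lower adjusted over the list alone. Cell migration and cytoskeleton genes were not shifted either (48 tested, adjusted p = 0.652), and ANXA3 was the 1 member lower adjusted over the list alone (0.00351). No member of these 5 lists passed over all genes tested in limma-trend. Unadjusted p-values under 0.05 fell on 28 higher and 12 lower genes, summed over the lists. Among all 12701 tested genes these numbers were 1172 and 917.

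The hypoxia list gave the smallest camera p-value among the lists tested, whereas in fry it did not pass for a common direction (adjusted p = 0.0595). Of 26 tested hypoxia and HIF target genes, 14 were higher and 0 lower adjusted over the list alone, against 0 over all genes (limma-trend, 16 higher at an unadjusted p under 0.05). ANGPTL4, a secreted regulator of lipoprotein lipase, went from 3.98 to 14.7 FPKM, and the collagen prolyl hydroxylase gene P4HA1 from 24.5 to 48.4. NDRG1 had 44.0 and 88.2 FPKM, the oxygen-sensing hydroxylase gene EGLN3 2.22 and 5.14, and ADM, the adrenomedullin gene, 50.6 and 77.7. BHLHE40, PLOD2, PPFIA4, BNIP3L, EPAS1, INSIG2, ANKRD37, KDM3A and P4HA2 were the others. VEGFA had 25.0 and 27.8 FPKM and HIF1A 29.4 and 31.2, and neither passed. The list's median log2 change was 0.43, with 0.36 in KO replicate 1 and 0.40 in KO replicate 2 (camera, adjusted p = 3.04e-10; adjusted p = 0.408 with an estimated correlation).

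Glycolysis genes were shifted upwards (22 tested, median log2 change 0.10, adjusted p = 0.0210; adjusted p = 0.7825 with an estimated correlation), with ENO2 (30.1 and 51.9 FPKM), HK1, PFKFB4 and the glucose transporter gene SLC2A1 (45.9 and 70.7) higher adjusted over the list alone. The median of that list was -0.02 in KO replicate 1 and 0.24 in KO replicate 2, and its call ended without KO replicate 2 (adjusted p = 0.712). Nuclear-encoded oxidative phosphorylation genes had medians of -0.01 and 0.22 in the same order, and ribosomal protein genes -0.03 and 0.26. Both passed as lists (77 and 75 tested, adjusted p = 0.0101 and 0.0128; adjusted p = 0.7825 and 0.796 with an estimated correlation), with 0 members past the threshold over the list alone. Without KO replicate 2 both turned downwards (0.695 and 0.430). The oxidative phosphorylation call also ended without EV control replicate 2 (0.188), and the ribosomal call without EV control replicate 1 (0.0939) or 2 (0.299).

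Glutamate, glutamine and D-amino acid metabolism, the area of metabolism in which DGLUCY acts, gave changes in both directions. Of 35 tested genes, 4 were higher and 5 lower adjusted over the list alone, against 0 over all genes (limma-trend, 6 higher and 7 lower at an unadjusted p under 0.05). GOT1, the cytosolic aspartate aminotransferase gene, went from 48.4 to 72.1 FPKM, and the glutamate transporter gene SLC1A1 from 4.84 to 10.8, with GAD1 and GGT1 also higher. Lower genes included the cystine-glutamate exchanger gene SLC7A11 (7.95 and 4.09 FPKM), SLC1A3, GCLM and CAD. The list was not shifted on balance (adjusted p = 0.972), whereas in fry it passed for change in either direction (adjusted p = 0.0108). Fatty acid oxidation genes (29 tested, adjusted p = 0.0557) and tricarboxylic acid cycle genes (33 tested, 0.982) were not shifted. Fatty acid oxidation passed without EV control replicate 1 (0.0486) and without KO replicate 1 (0.00852).

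Lists tied to proliferation lay lower in the KO libraries. G2/M and mitosis genes had a median log2 change of -0.16 (46 tested, adjusted p = 2.72e-07; adjusted p = 0.654 with an estimated correlation), nearly equal in the KO libraries at -0.18 in each. PLK1, a mitotic kinase gene, had 57.0 and 45.5 FPKM and the kinesin gene KIF11 18.5 and 14.6. No G2/M gene passed over the list alone or over all genes in limma-trend, with 1 higher and 15 lower at an unadjusted p under 0.05. S phase genes had medians of -0.24 in KO replicate 1 and -0.04 in KO replicate 2 (45 tested, adjusted p = 0.000265; adjusted p = 0.7825 with an estimated correlation), and their call ended without KO replicate 1 (0.524). MCM2, a subunit of the replicative helicase, had 64.0 and 51.5 FPKM, and 0 members passed over the list alone.

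Replication-dependent histone genes, which also report on RNA quality because most of their transcripts lack the poly(A) tail used to select mRNA, lay lower too (11 tested, median log2 change -0.37, adjusted p = 0.000657; adjusted p = 0.408 with an estimated correlation). HIST1H2BK, HIST1H1C and HIST1H2AC were lower adjusted over the list alone, as members of a family of near-identical genes whose reads can be split.

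Genes of the immediate early response were shifted upwards (32 tested, median log2 change 0.23, adjusted p = 0.00243; adjusted p = 0.408 with an estimated correlation). The phosphatase gene DUSP5 (44.2 and 94.7 FPKM) and the zinc-finger factor gene EGR1 (11.4 and 31.8) were higher adjusted over the list alone. FOS had 3.67 and 19.1 FPKM, JUNB 47.3 and 76.1, and DUSP6 64.3 and 124, none of which passed. The KO libraries were unequal for FOS, with log2 changes of 0.75 in KO replicate 1 and 2.79 in KO replicate 2. EGR1 had 23.7 and 39.9 FPKM in the same order. Interferon-stimulated genes were shifted upwards (34 tested, median log2 change 0.17, adjusted p = 0.0128; adjusted p = 0.408 with an estimated correlation), with PSMB9, UBE2L6, IFI27 and the RNA sensor gene IFIH1 higher adjusted over the list alone. That call ended without KO replicate 1 (0.151). Mitochondrial unfolded protein response genes lay lower (25 tested, median log2 change -0.15, adjusted p = 0.0101; adjusted p = 0.7825 with an estimated correlation), with the chaperonin gene HSPD1 at 1032 and 798 FPKM and 0 members past the threshold over the list alone, and their call ended without KO replicate 1 (0.524).

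Notch pathway genes were not shifted as a list (17 tested, adjusted p = 0.504), but NOTCH3 (6.27 and 9.33 FPKM), HES2 and HES6 were higher adjusted over the list alone. The lists for NRF2 and oxidative stress (29 tested, adjusted p = 0.0557), ATF4 and the integrated stress response (31, 0.0929), HLA class I presentation (13, 0.192), cholesterol biosynthesis (34, 0.385), NF-κB (15, 0.572), the endoplasmic reticulum unfolded protein response (23, 0.620), YAP/TEAD targets (21, 0.652) and TGF-β and BMP targets (20, 0.682) did not pass and held 0 members past the threshold over the list alone. Without KO replicate 2 the NRF2 list (4.06e-05) and the ATF4 list (0.0165) passed, both downwards, and without KO replicate 1 the HLA class I list (0.00409) and the cholesterol list (0.0440) passed, both upwards. The median and the mean log2 change had opposite signs for the Notch, stem cell, intestinal differentiation, cell migration, glutamate and tricarboxylic acid cycle lists, all with medians between -0.03 and 0.02; the camera direction followed the mean except in the tricarboxylic acid cycle list.

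Markers of cells that a culture of this line should not hold were mostly below the minimum level. Of 20 fibroblast and endothelial markers 1 was tested, PCOLCE, with 2.93 and 3.93 FPKM (list-alone adjusted p = 0.0489). Of 20 leukocyte markers 3 were tested, of which CORO1A was higher adjusted over the list alone (1.10 and 2.41 FPKM, 0.0224). Of 20 markers of kidney, cervix and hepatocyte lines 4 were tested and 0 passed in limma-trend, at an unadjusted p under 0.05 too. Mitochondrially encoded transcripts were not analysed here.

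Over the 32 lists tested, 14 passed with the preset correlation, 9 upwards and 5 downwards. With an estimated correlation 0 passed (smallest adjusted p = 0.408). In that setting p-values rose even where the estimated correlation lay below the preset 0.01. For the histone list that correlation was -0.087, and the unadjusted camera p went from 0.000103 to 0.0553. Among lists that passed, far higher estimates came from the ribosomal (0.93), oxidative phosphorylation (0.77), glycolysis (0.63), S phase (0.58) and mitochondrial unfolded protein response (0.53) lists. Their unadjusted camera p in that setting was 0.697, 0.653, 0.5265, 0.435 and 0.460, in the same order. The calls of these lists thus rest on the low preset correlation. For the other lists, with few residual degrees of freedom, the setting does not show whether correlation within lists made the calls. In fry 1 list passed for a common direction and 21 for change in either direction. The latter makes no comparison with other genes. Of all 12701 tested genes, 1172 were higher and 917 lower at an unadjusted p under 0.05 (limma-trend), so these 21 lists are not thereby set apart.

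**Figure D2:**
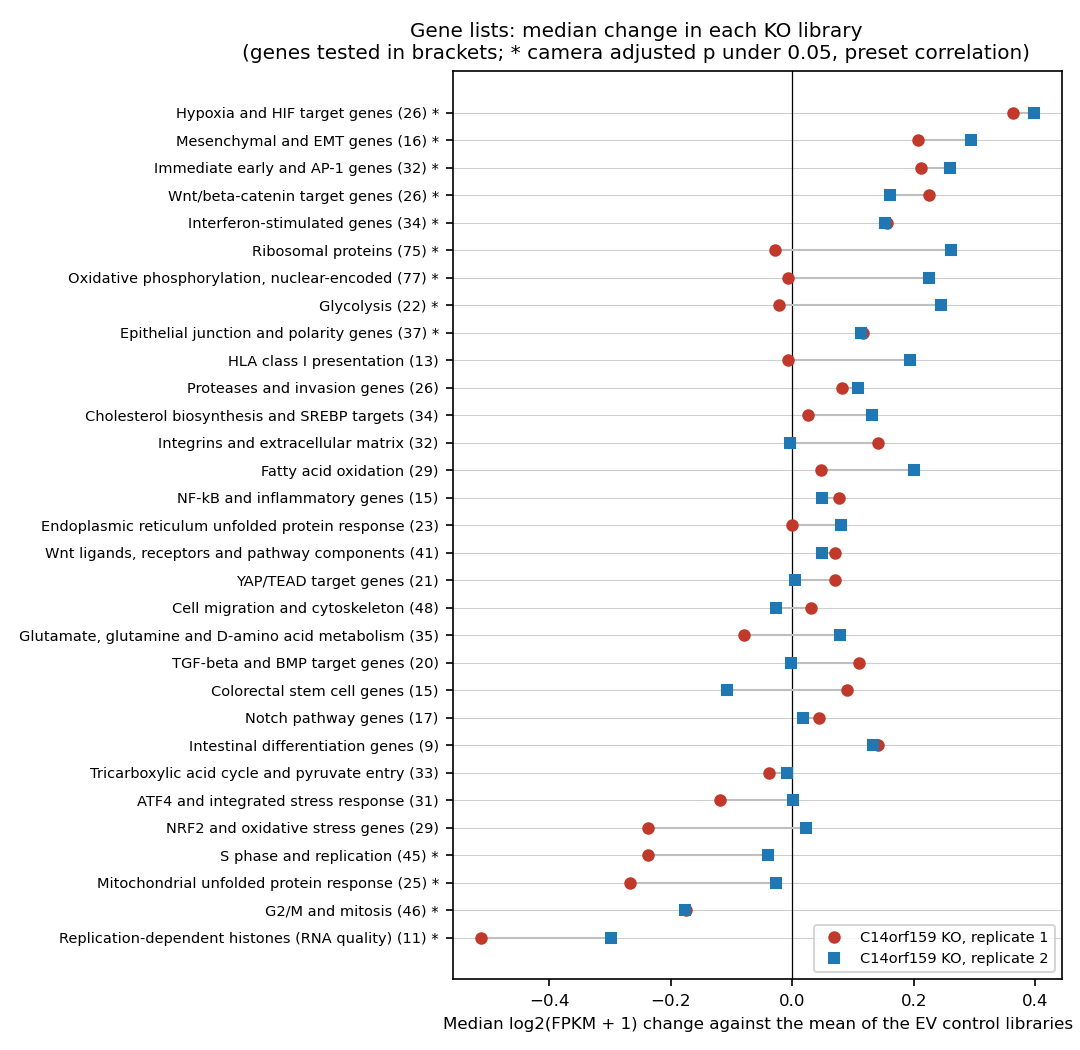
Median log2(FPKM + 1) change of each gene list against the EV control mean (x axis), 1 symbol per KO library, with lists on the y axis and the genes tested in brackets. The hypoxia list lies at 0.36 and 0.40, whereas the ribosomal protein list lies at -0.03 in KO replicate 1 and 0.26 in KO replicate 2.

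Because the KO libraries differed in C14orf159 itself, its neighbours on chromosome 14 were examined, a comparison chosen after seeing the data. The best single split of each chromosome was sought. Chromosome 14 in KO replicate 1 scored 21.3, against at most 7.12 for any other split. The stretch starts at that split, so its start, counts and interval in KO replicate 1 rest on the values that placed it. Genes from TTC7B, the gene before C14orf159 among those with a mean of at least 5 FPKM, to the last such gene of the chromosome, C14orf80, were lower in KO replicate 1. Of the 66 expressed genes in this stretch other than C14orf159, 65 were lower in KO replicate 1 than the EV control mean, and EVL was the exception (log2 change 0.66). Among them were the Dicer ribonuclease gene DICER1 (-0.86), the kinase gene AKT1 (-0.86), the chaperone gene HSP90AA1 (-1.27), the transcription factor gene YY1 (-0.69) and the dynein heavy chain gene DYNC1H1 (-0.91). The median gene of the stretch stood at 56.6% of its EV control level in KO replicate 1 (95% bootstrap interval 53.9% to 58.3%) and at 102.9% in KO replicate 2 (96.2% to 110.1%). C14orf159 itself stood at 15.5% and 66.2%.

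The 230 expressed genes on the rest of chromosome 14 had a median of 103.9% in KO replicate 1 and 102.3% in KO replicate 2. The split placed the step directly before TTC7B, in the gene order of RefSeq. Outside the stretch, the most extreme median over 41 neighbouring genes anywhere in KO replicate 1 was 0.22 on the log2 scale. That window lay on the same chromosome before the stretch, from PSMA3-AS1 to SLC39A9, opposite in direction to the -0.78 of the stretch. In KO replicate 2 the most extreme median outside the stretch was 0.24. From TTC7B to the end of the chromosome 97 genes were tested, those with a mean under 5 FPKM included. Of these, 74 were among the 881 genes called lower with KO replicate 1 as the lone KO library (8.4% of those calls).

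**Figure D3:**
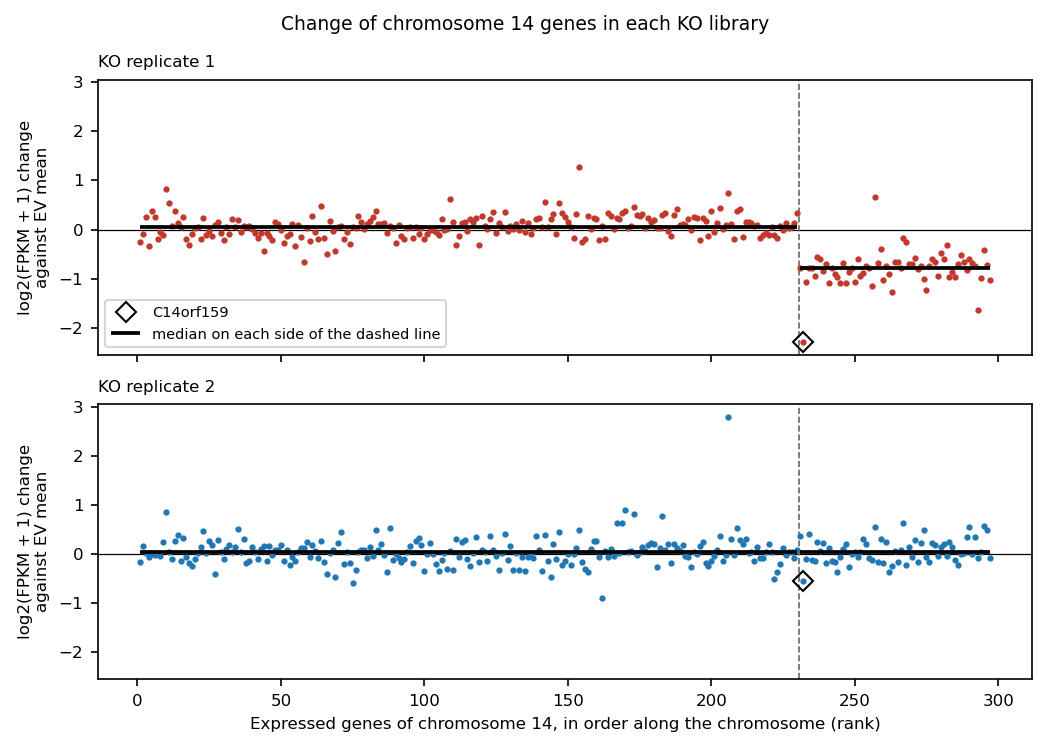
Log2(FPKM + 1) change against the EV control mean (y axis) of the expressed genes of chromosome 14 in their order along the chromosome (x axis, rank), for KO replicate 1 (top) and KO replicate 2 (bottom); bars are medians on each side of the dashed line, drawn directly before TTC7B, and the diamond is C14orf159. To the right of the line, 65 of 66 genes other than C14orf159 lie below 0 in KO replicate 1, against 30 of 66 in KO replicate 2.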

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

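The fits without small RNA genes, with the GC content and length correction and without distal chromosome 14 genes were chosen after the results were seen. The counts of 7 higher and 7 lower genes became 3 and 3 without a filter on low values. Without the trend 3 were higher and with quantile normalization 4 were lower. Without small RNA genes the counts were 0 and 0 (limma-trend, 2171 genes at an unadjusted p under 0.05). The other scalings, pseudocounts, filter and robust fit stayed within 1.5 times. Leaving out each library in turn gave 6 to 1381 higher and 5 to 881 lower genes, and 1629 lower and 2333 or 1453 higher genes without small RNA genes and without KO replicate 1 or 2. A lone KO library takes its spread from the EV controls, whose replicates differed less than the KO replicates.

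With a replicate block 4 genes were higher and 8 lower, and UGP2, ACSL5 and TMEM74B had adjusted p = 0.0535, 0.0631 and 0.0520. The labels do not say that replicate numbers pair libraries, and the deviations of same-numbered libraries had a correlation of -0.0046 across genes.

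The number of lists past the threshold went from 14 to 0 with an estimated correlation and to 1 in fry, and was 12 to 14 on leaving out each library. The Wnt/β-catenin target list had adjusted p = 0.408 with an estimated correlation, 0.00703 to 0.0892 on leaving out each library, and 0.0824 without small RNA genes and KO replicate 1. C14orf159 kept its direction, from -2.30 to -0.55 on leaving out each library. Such fits leave a lone library in a group, and their p-values for this gene are not given. With small RNA genes left out too, its log2 change was -0.55 without KO replicate 1 and -2.30 without KO replicate 2.

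Without KO replicate 2 the oxidative phosphorylation and ribosomal lists turned downwards (adjusted p = 0.695 and 0.430; 0.641 and 0.401 without small RNA genes), as their medians were above 0 in that KO library alone. On leaving out each library their adjusted p ran from 3.16e-10 to 0.695 and from 5.32e-13 to 0.430, the lowest without KO replicate 1. Of 618 other list results under an alternative 515 kept direction and side of the threshold, 45 lost it, 25 gained it and 33 turned. Of 2649 results for named genes, without the few not reported here, 2163 kept both, 24 lost the threshold, 456 gained it and 6 turned. Apart from the oxidative phosphorylation and ribosomal lists, nothing that turned had passed in either analysis. The gains of named genes include those in settings with a lone KO library, which takes its spread from the EV controls. For the remaining changes the cause was not tested. A test on counts was not run, since the values are FPKM. Depth limits short and low genes most.

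Adjusted p is given for lists that turned. The tricarboxylic acid cycle list turned upwards in fry (0.532), without the trend (0.9835), with the replicate block (0.909), with the GC content and length correction (0.967) and without small RNA genes and KO replicate 1 (0.910). The glutamate list did so in fry (0.988), without the trend (0.9835) and without small RNA genes and KO replicate 1 (0.710). Turned downwards were intestinal differentiation without a filter on low values (0.899) and TGF-β and BMP targets at a filter of 5 FPKM (0.775). Without small RNA genes and KO replicate 1 the lists of Wnt components (0.932), integrins (0.900), YAP/TEAD targets (0.795), TGF-β and BMP targets (0.795) and stem cell genes (0.443) turned downwards. Without small RNA genes and KO replicate 2 cell migration (0.651) turned upwards, and HLA class I (0.7845) and cholesterol (0.704) downwards.

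Lists that turned without 1 library ran over the 4 libraries left out from 0.712 to 0.997 (tricarboxylic acid cycle), 0.387 to 0.997 (glutamate), 0.00455 to 0.887 (integrins), 0.3185 to 0.695 (cell migration), 0.00409 to 0.760 (HLA class I), 0.0440 to 0.760 (cholesterol), 0.416 to 0.891 (YAP/TEAD), 0.397 to 0.891 (TGF-β and BMP) and 0.0739 to 0.482 (stem cell). The log2 change of CD68 ran from -0.125 to 0.293, of PAX8 from -0.3065 to 0.00884 and of PAX2 from -0.1115 to 0.264. Without small RNA genes and KO replicate 2 CD68 (-0.125) and PAX8 (0.00884) turned alike.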

Other observations

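The overlap between the KO libraries and all tests below, except those of GC content and length, were chosen only after the results they measure had been seen.

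Each KO library was compared alone with the EV controls, and the calls were then matched. A total of 375 genes were higher in both KO libraries and 216 lower in both, of 799 and 1381 higher and 881 and 841 lower in KO replicates 1 and 2. Another 69 genes went in opposite directions. Independent lists would share 86.9 and 58.3 genes, but these lists have both EV controls in common, which can add shared calls by itself, and how many was not determined. Among genes higher in both were the metalloprotease gene ADAM19 (5.67 and 23.6 FPKM in EV control and KO cells), the Wnt carrier gene WLS (25.5 and 38.8), the ligand genes WNT3A and WNT6, the receptor gene MET (37.6 and 52.7) and the epithelial genes CLDN4 and EPCAM. Among genes lower in both were the fatty acid synthesis genes FASN (186 and 141 FPKM) and ACACA (42.5 and 34.0), the serine synthesis gene PSAT1 (106 and 83.1), the one-carbon enzyme gene MTHFD2 (181 and 146), and the amino acid transporter gene SLC7A5 (137 and 103). NQO1 (222 and 171) and the efflux pump gene ABCC2 (89.2 and 45.9) were lower in both as well. The hypoxia list gave 12 of its 26 genes to the shared higher set and the immediate early list 8 of 32.

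The stretch of chromosome 14 from TTC7B onwards, lower in KO replicate 1, was weighed first. GC content or length is argued against, since after correction for both the median log2 change of the stretch was -0.753. A chance run of neighbours is argued against too, since the most extreme window of 41 genes outside it reached 0.223, upwards and on the same chromosome. Loss of 1 copy of the stretch is a candidate explanation, as the median gene stood at 56.63% of the EV control level with 65 of 66 genes lower. The interval of 53.9% to 58.3% lies above the level that loss of 1 of a pair of equal copies would leave. It holds no uncertainty in the scaling between libraries, and the rest of chromosome 14 stood at 103.9%. The interval therefore cannot decide for or against such a loss. Silencing without loss, a mixed population and a difference that predates the knockout were not tested, and no DNA data were analysed here.

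The small RNA calls were weighed next. All 10 showed whole-number ratios between replicates, where 5.89% of 10458 longer genes did, and in 6 of them the numbers were equal, which is what few fragments on very short genes would give. In the other 4 (MIR6126, SNORA5C, MIR671 and SNORA60) the numbers differed, as with SNORA5C at 14.3 and 27.8 FPKM in the EV controls. The calls may thus come from few fragments on very short genes, with a small spread between replicates in the 6 alone. A change in these RNAs by the knockout stays open and untested, since libraries selected for poly(A) measure them poorly.

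The higher hypoxia genes were weighed last. After correction for GC content and length the list's median log2 change was 0.483, which argues against both as the whole cause. An effect of the knockout and a difference in cell density or oxygen at harvest may each account for it, and neither was tested, so this remains a hypothesis.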
